A study of Danio rerio with 24 samples.

How the data were processed

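RNA from caudal fins of zebrafish (Danio rerio, AB strain) was measured on 24 Affymetrix zebrafish expression arrays in 8 groups of 3 replicates. Larval fins were unamputated at 2 days post fertilization or collected 1, 2 or 3 days post amputation (dpa), with 150 fins pooled per replicate. Adult fins were unamputated or collected at 1, 3 or 5 dpa, with 10 male fish pooled per replicate. The labels disagree in 2 places: the text for the adult unamputated arrays gives collection at 1, 2 and 3 dpa, and all 6 larval unamputated and 1 dpa arrays are numbered replicate 1 in their source names. The titles were followed in both. Per the labels, larval samples started from 100 ng of RNA in a kit with a second amplification cycle, and adult samples from 2.5 µg in a single-cycle kit. Larval fins at 2 and 3 dpa had been exposed to the vehicle DMSO, adult regenerating fins came from fish injected with vehicle liposomes, and no vehicle was stated for the other groups. Age, kit and RNA input therefore changed together, and in larvae the day post amputation was also the age of the fish.

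The arrays were processed by the authors with GCRMA per the submitters' processing notes, which gave no version. The deposited values are a ratio on a linear scale, each probe set divided by a reference of its own. Of 15617 probe sets, 9600 held exactly 1 value of 1 among the 24 arrays, and 12198 had 10 to 13 arrays below 1. Differences between arrays can be read from such values, while the absolute level of a probe set cannot. Every rule below that was meant to sort probe sets by brightness therefore sorts them by ratio. Values were log2 transformed and otherwise used as deposited. The arrays carry no counts, and their number limits the precision.

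After 115 control probe sets were set aside, 15502 probe sets were tested. Of these, 10795 matched 1 gene symbol, 135 matched several and 4572 matched none, which gave 8793 distinct genes. A gene with more than 1 probe set was represented by the probe set with the highest mean over all arrays. With ratios, a high mean can come from large rises in some groups, so this choice was not independent of the changes. Read from another probe set, 128 named changes kept direction and call, 64 were no longer called, 2 were newly called and 15 reversed. Linear models were fitted with limma (version 3.58.1, R version 4.3.3) to the 12 arrays of each age, and to all 24 arrays for the difference between adult and larval change. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold, which is 1 on the log2 scale. In what follows, rose and fell refer to called probe sets only, and errors are the standard error of the model unless given as SD. The groups, comparisons, gene lists, thresholds and most alternatives were fixed before the data were examined.

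Each day after amputation was compared with unamputated fin of the same age, successive days were compared with one another, and the adult change was compared with the larval change at 1 and 3 dpa. Shared calls were counted where a probe set was called in both ages in one direction, and were set against the count for independent calls by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over 6 tests. Because the 3 days of an age share their unamputated arrays, 20 data sets without any change were simulated for each age. Calls at all 3 days averaged 0 in simulated larval data and 0.05 in simulated adult data, with 1 as the highest count. Adjusted p values call almost nothing in data without change, so these low counts do not measure the effect of the shared arrays. At an unadjusted limma p under 0.05, averages of 84.05 larval and 84.4 adult probe sets passed in 1 direction at all 3 days.

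Lists of genes were fixed for 27 subjects: retinoic acid, Wnt, Fgf, Hedgehog, Notch, and the Bmp, activin and Tgfb pathway, blastema and fin regeneration genes, extracellular matrix, matrix proteases, cell cycle and DNA replication, inflammation, leukocytes, epidermis, bone, skeletal muscle, pigment cells, neurons and glia, erythrocytes, endothelium, notochord and cartilage, median fin fold, aryl hydrocarbon receptor targets, chaperones, ribosomal proteins, mitochondrial respiration, proteasome and oxidative stress. The ribosomal and proteasome lists were made by symbol pattern, which also took in kinases such as rps6ka1 and the gene psmc3ip. Each list was tested against the other genes with camera in limma at a preset correlation of 0.01, adjusted over 162 tests, and 72 passed. With the correlation estimated from the data, 0 of these passed. Even skeletal muscle in larvae at 2 dpa, with a median log2 change of −3.24, did not pass it. A setting that passes no list cannot tell a shifted list from others. Failing it therefore weighs neither for nor against a list. When the 12 arrays of each age were assigned to groups at random, the median number of passing tests was 48 over the other assignments of 100, with quartiles of 40.5 and 55.5. The preset camera p is therefore small for correlated genes whatever the grouping. Counts of called genes are given beside it, and have to be read against the calls over all 15502 probe sets. Those were 622, 1945 and 1641 in larvae at 1, 2 and 3 dpa, and 2492, 2215 and 1778 in adults at 1, 3 and 5 dpa. The median, the mean and the test differed in sign in 23 of 162 cases, of which 0 passed.

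Genes were named by a rule: the probe set carried 1 symbol, the higher of its group means lay above the median of all values, and the gene was among the 10 largest rises or falls against unamputated fin, the 5 largest in a step between days, the 10 largest shared changes, the 5 largest differences in each direction, or up to 4 called members and 1 uncalled member of a list. The gene aldh1a2 was named throughout. Other named genes are pointed out as chosen after their values were seen.

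The procedure was tested on simulated data with probe sets changed by known amounts. At a true log2 change of 2, between 80.6% and 100% of changed probe sets were called across the 12 comparisons, and 1 to 9 unchanged probe sets were called per comparison. In simulated lists, the 1 shifted list was called in each of the 6 comparisons and 0 of the 26 others was. Noise was drawn independently for each probe set, so these simulations do not show how the list test behaves with correlated genes.

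Replicate labels were checked for pairing by correlating residuals between groups. Arrays of adult 3 and 5 dpa with the same letter had r across probe sets of 0.433, 0.216 and 0.156 for a, b and c. Larval pairs of the same number reached up to 0.197, and arrays with different labels were not compared. Pairing was therefore not established. The letter b of adult 1 dpa had r of 0.405 with b of adult 5 dpa and of 0.048 with b of adult 3 dpa. Probe sets are not independent replicates in any correlation given across them. Alternatives tried were the minimum fold change, a floor on low values, a filter on low means, quantile normalization, centring of arrays, a variance trend, the arrays in the fit, a block for replicate labels, other probe sets of a gene, the mean of a gene's probe sets, other settings of the list test, and leaving out each array in turn. The control probe sets for added RNA were summarised per array. So was the log2 difference between the 3' and 5' control probe sets of gapdh, which in signal intensities is a check of RNA integrity. Here each is a ratio to its own reference, so the difference can be compared between arrays but does not itself measure integrity. Group means of the difference ran from −2.22 to −1.50 in adults and from −0.03 to 0.29 in larvae, and labelling kit and RNA input also differed between the ages. Within adult groups the gapdh difference ran from −2.55 to −0.99 at 1 dpa and from −2.30 to −0.55 at 3 dpa. Its bearing on the counts was not tested. Figures were drawn with matplotlib 3.10.9 in Python.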

Results

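Expression was measured in caudal fins of zebrafish larvae and adults before and after amputation, on 24 arrays in 8 groups of 3. The larval groups were unamputated fin at 2 days post fertilization and regenerating fin on days 1, 2 and 3 after amputation (dpa, days post amputation). The adult groups were unamputated fin and fin at 1, 3 and 5 dpa. Comparisons within an age set 3 arrays against 3, the difference between adult and larval change drew on 4 groups of 3, and 15502 probe sets were tested in each. Replicates of a group correlated across probe sets with r between 0.793 and 0.939, apart from the larval 3 dpa arrays, where r ran from 0.629 to 0.808 and replicate 3 stood apart. The comparisons with unamputated fin asked which genes change as a fin regrows at each age, and those between ages asked how far larval and adult regrowth share these changes, as the series title states.

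**Figure D1:**
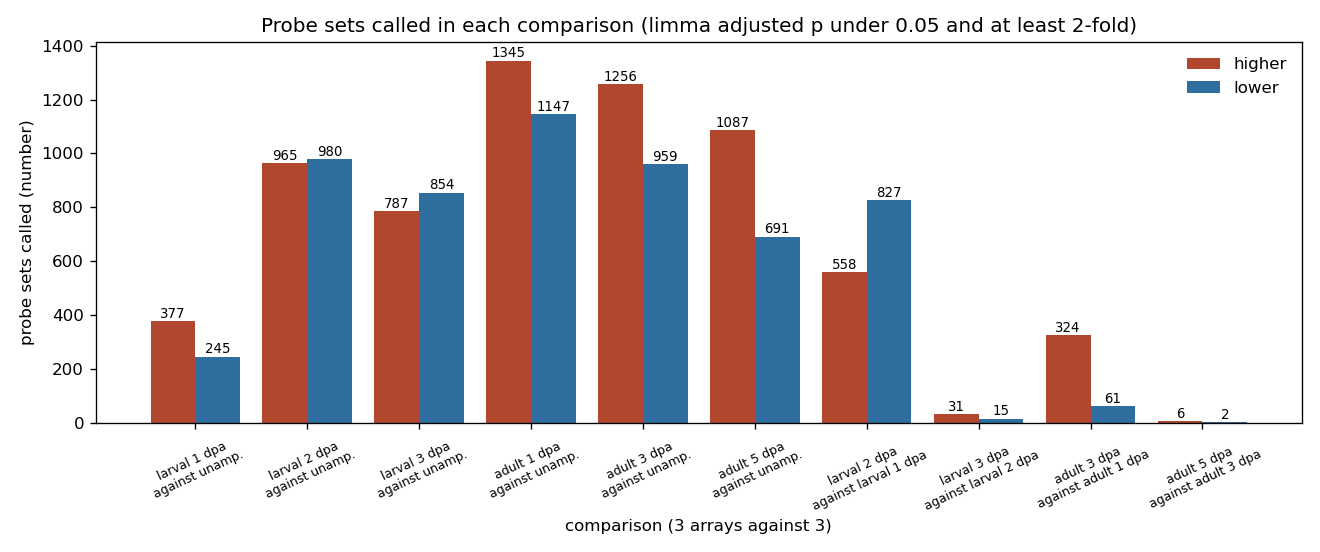
Number of probe sets called higher (red) and lower (blue) in each of 10 comparisons of 3 arrays with 3, at a limma adjusted p under 0.05 and at least 2-fold. Steps between late days, with 46 probe sets in larvae and 8 in adults, called far fewer than comparisons with unamputated fin.

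In larval fin at 1 dpa the cathepsin L gene ctsl.1, which encodes a lysosomal protease, rose by 7.66 ± 0.48 on the log2 scale (limma adjusted p = 1.7e-05). Genes of phagocytes rose with it, among them marco, a macrophage scavenger receptor, by 2.79 ± 0.33, and spi1b, a transcription factor of myeloid cells, by 2.41 ± 0.38. The retinaldehyde dehydrogenase gene aldh1a2, whose product makes retinoic acid, rose by 3.55 ± 0.37 (limma adjusted p = 0.00027). The embryonic globin gene hbbe3 fell by 5.07 ± 0.65, whereas its relatives hbbe2 and hbae3 rose by 3.14 ± 0.26 and 2.09 ± 0.27. Falls were also called for ppp1r3b, a regulator of glycogen synthesis (−3.13 ± 0.21), rcan3, a regulator of calcineurin (−2.58 ± 0.14), and the hypoxia factor epas1a (−2.34 ± 0.18). In total 622 probe sets were called, 377 higher and 245 lower. The majority turned with a floor on low values (103 higher, 153 lower) and with probe sets above the median mean (155 higher, 167 lower).

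Of 31 leukocyte genes measured, 12 rose, 1 fell and 18 were not called at 1 dpa in larvae (13 rose and 1 fell adjusted over the list alone), with a camera adjusted p = 0.00092, and 0.42 with an estimated correlation. Among 21 matrix proteases and inhibitors, 6 rose and 0 fell, in 6 cases also adjusted over the list alone. The 3 largest rises were those of the cathepsins ctss2.1 (3.50 ± 0.51), ctsba (1.46 ± 0.17) and ctsd (1.36 ± 0.19), and the list had a camera adjusted p = 0.00027, or 0.11 with an estimated correlation. Small shifts without many called genes were seen in the 87 genes of mitochondrial respiration, with a median of 0.36 and 1 gene called (1 adjusted over the list alone), and in the 79 ribosomal protein genes, with a median of 0.21 and 0 genes called (0 adjusted over the list alone). Their camera adjusted p values were 8.6e-08 and 3.4e-06, and 0.54 and 0.58 with an estimated correlation. The 24 genes of the median fin fold, the larval fin's embryonic form, had a median of −0.52, with 2 genes lower, lama5 (−1.17 ± 0.16) and dlx2b (−1.13 ± 0.26), in both counts (camera adjusted p = 3.5e-07, 0.29 with an estimated correlation). In the epidermis list of 53 genes, krt15 rose by 2.83 ± 0.32 while the cornified envelope gene evplb fell by 2.19 ± 0.24. That list had 5 rises and 4 falls, the same numbers adjusted over the list alone (camera adjusted p = 0.00048 toward lower, 0.39 with an estimated correlation).

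Skeletal muscle genes had the lowest median of the 27 lists at 2 and 3 dpa in larvae. The slow myosin gene smyhc1 had a change of −7.51 ± 0.61 (limma adjusted p = 9.3e-06), and the muscle calcium pump gene atp2a1 by −7.24 ± 0.60. Of 57 muscle genes, 44 fell, 1 rose and 12 were not called (44 and 1 adjusted over the list alone), with a median of −3.24 and a camera adjusted p = 5.5e-20, or 0.38 with an estimated correlation. At 3 dpa, 42 fell and 0 rose (42 and 0 adjusted over the list alone), with smyhc1 at −8.28 ± 0.61. At 1 dpa the same list had 3 rises, 0 falls and a median of 0.42. Genes of other tissues of the trunk fell on the same days as muscle. Among 24 notochord and cartilage genes, 9 fell at 2 dpa and 11 at 3 dpa, including the collagen genes col2a1a (−7.67 ± 0.43 and −8.65 ± 0.43) and col9a1b (−7.46 ± 0.36 and −7.99 ± 0.36), and 1 rose on each day. Counts adjusted over the list alone were 9 and 11 lower. The list's camera adjusted p was 1.9e-06 at 2 dpa, and 0.085 with an estimated correlation.

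Erythrocyte genes followed muscle as well, with 9 of 19 lower at 2 dpa and 8 at 3 dpa (9 and 8 adjusted over the list alone), such as the anion exchanger slc4a1a (−5.01 ± 0.47 and −4.83 ± 0.47). The camera adjusted p was 0.00027 at 2 dpa, and 0.11 with an estimated correlation. Of 20 endothelial genes, 5 fell on each day (5 adjusted over the list alone), among them the vascular receptor kdrl (−3.30 ± 0.28 and −3.54 ± 0.28), with a camera adjusted p = 0.0028 at 2 dpa and 0.39 with an estimated correlation. In the list of 33 neuron and glia genes, 5 fell on each day (5 adjusted over the list alone), including the neuronal RNA-binding gene elavl3 (−2.67 ± 0.44 and −2.33 ± 0.44), with a camera adjusted p = 0.00035 at 2 dpa and 0.38 with an estimated correlation. The Hedgehog genes shha (−4.76 ± 0.36 at 2 dpa), which the notochord also expresses, and hhip (−3.97 ± 0.27) were the 2 of 12 pathway genes that fell at 2 and at 3 dpa (2 adjusted over the list alone, camera adjusted p = 0.082 at 2 dpa, 0.55 with an estimated correlation). Of 27 Notch genes, dlb, dla and hey1 were the 3 that fell on both days, with dlb at −2.67 ± 0.39 and −3.43 ± 0.39 (3 adjusted over the list alone, camera adjusted p = 0.038 at 2 dpa, 0.39 with an estimated correlation). The epidermis, a tissue of the fin itself, had 15 of 53 genes lower and 5 higher at 2 dpa and 14 lower and 2 higher at 3 dpa, the same counts adjusted over the list alone. Its camera adjusted p was 0.0031 and 0.0012 toward lower, and 0.45 and 0.42 with an estimated correlation.

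Inflammation and early response genes were among those that rose in larval fin at 2 and 3 dpa. The cytokine signalling inhibitor socs3a rose by 3.86 ± 0.29 at 2 dpa and 3.16 ± 0.29 at 3 dpa, and the early response gene junba by 3.42 ± 0.39 and 2.99 ± 0.39. The complement gene c4b rose by 4.11 ± 0.82 and 4.71 ± 0.82, and tat, a tyrosine-degrading enzyme that glucocorticoids induce, by 5.15 ± 0.92 and 6.88 ± 0.92. Of 49 inflammation genes, 22 rose and 2 fell at 2 dpa (22 and 2 adjusted over the list alone), and 18 rose and 2 fell at 3 dpa. The camera adjusted p was 4.1e-05 at 2 dpa, and 0.39 with an estimated correlation. The chemokine gene cxcl12b went the other way, at −5.64 ± 0.37 and −5.48 ± 0.37. Leukocyte genes had 9 rises at 2 dpa and 10 at 3 dpa, with 1 fall on each day in the lysozyme gene lyz (−3.51 ± 0.70 and −4.23 ± 0.70). With only the genes above the median mean, the leukocyte list's direction reversed on both days, with camera adjusted p of 0.86 and 0.71. Of the matrix proteases, 13 rose at 2 dpa and 11 at 3 dpa (13 and 12 adjusted over the list alone), such as the bone cathepsin ctsk (2.14 ± 0.28 and 1.86 ± 0.28), and the list had a camera adjusted p = 9.9e-06 at 2 dpa, or 0.085 with an estimated correlation. The gene aldh1a2 reached 5.63 ± 0.37 at 2 dpa and 4.70 ± 0.37 at 3 dpa.

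Totals were 1945 called probe sets at 2 dpa (965 higher, 980 lower) and 1641 at 3 dpa (787 higher, 854 lower). With a floor on low values the splits were 423 higher and 607 lower at 2 dpa and 292 and 551 at 3 dpa. The majority turned to higher with no minimum fold change (2565 and 2334, 2246 and 2125). It also turned with quantile normalization (966 and 870, 784 and 748) and without probe sets under 1 in 15 or more arrays (968 and 900, 790 and 784). Vehicle exposure, fish age and day post amputation all separated the 2 and 3 dpa groups from unamputated larval fin, and no age-matched unamputated larvae were measured.

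Camera p values with the preset correlation need care in all lists here. Of 162 list tests 72 passed, but with arrays assigned to groups at random a median of 48 did and the highest was 71. With an estimated correlation 0 passed, skeletal muscle included, so that setting does not tell the lists apart either. Of the 162 cases, 23 had a median, mean or test of differing sign, such as retinoic acid in adults at 1 dpa (median −0.36, mean 0.01), and 0 of these passed.

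Cell cycle genes fell in larvae at 2 and 3 dpa and rose in adults at all days. In larval fin at 2 dpa, 54 of 94 fell, 1 rose and 39 were not called (54 and 1 adjusted over the list alone), with the kinesin gene kif11 at −2.46 ± 0.30 and the cytokinesis gene prc1a at −2.86 ± 0.41 (camera adjusted p = 2.2e-21, 0.25 with an estimated correlation). At 3 dpa, 23 fell and 0 rose (23 adjusted over the list alone), and at 1 dpa 0 were called in either count (camera adjusted p = 0.044 toward higher, 0.76 with an estimated correlation). From 2 to 3 dpa 14 of these genes rose and 0 fell (16 rose adjusted over the list alone), among them mcm4 (1.54 ± 0.10) and pcna (1.47 ± 0.14), both parts of the replication machinery, with a camera adjusted p = 5.2e-28, or 0.18 with an estimated correlation. The growth factor gene igf2b rose by 1.91 ± 0.34 in the same step, which called 46 probe sets, 31 higher and 15 lower. These were 0 higher and 6 lower with a floor on low values and 4 higher and 11 lower with probe sets above the median mean. That count was 2 with the 2 groups compared alone, 23 without larval 2 dpa replicate 1, 29 without larval 2 dpa replicate 3 and 122 without larval 3 dpa replicate 1. The step from 1 to 2 dpa called 1385 probe sets, 558 higher and 827 lower (1961 and 1668 with no minimum fold change), with changes of −8.48 ± 0.43 in col2a1a, −8.09 ± 0.61 in smyhc1 and 2.99 ± 0.50 in ecrg4a. In that step 59 cell cycle genes fell and 0 rose (59 adjusted over the list alone).

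**Figure D2:**
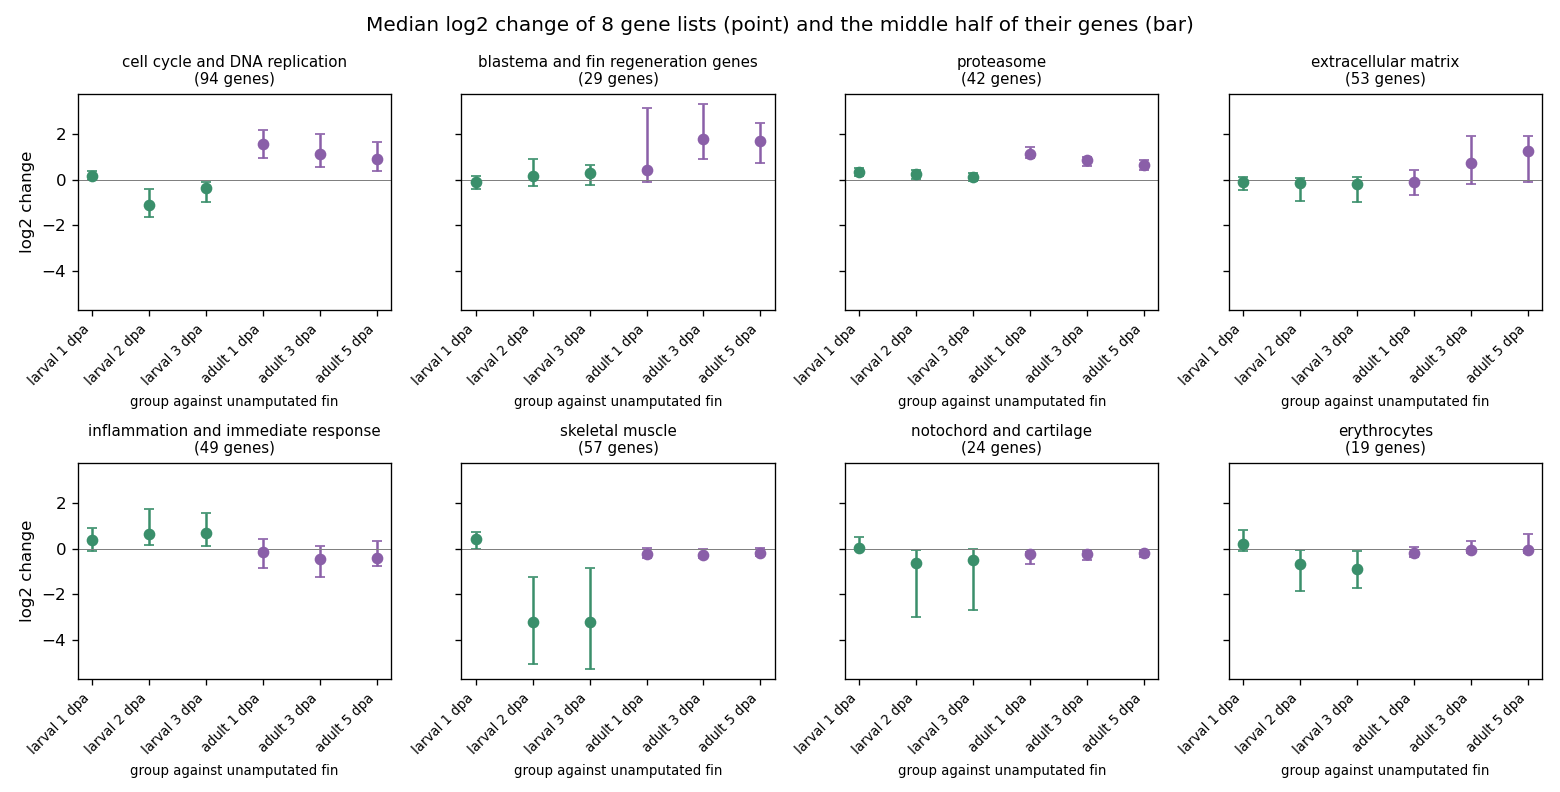
Median log2 change (points) of 8 gene lists against unamputated fin of the same age, with bars from the lower to the upper quartile of each list's genes, for larval (green) and adult (purple) fin at each day. Skeletal muscle stood at −3.24 at larval 2 dpa, and cell cycle genes lay below 0 at larval 2 and 3 dpa and above 0 at all adult days.

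In adult fin at 1 dpa the 3 largest rises among named genes were those of ntrnl2 (6.71 ± 0.49), jac4 (6.40 ± 0.55) and tph1b (5.67 ± 0.59), which encodes tryptophan hydroxylase, the first enzyme of serotonin synthesis (limma adjusted p = 0.00019). The coagulation factor gene f5 rose by 5.20 ± 0.35 and the protease inhibitor gene timp2b by 4.31 ± 0.34. The wound matrix gene tncb, a tenascin, rose by 4.13 ± 0.95, although another probe set of the gene read −0.38. Among the 10 largest falls were tat (−4.58 ± 0.85), cyp1a, a detoxifying target of the aryl hydrocarbon receptor (−4.47 ± 1.55), the bone collagens col10a1b (−3.89 ± 0.58) and col10a1a (−3.73 ± 0.43), the chemokine cxcl12a (−3.70 ± 0.59), and the circadian clock genes ciarta (−4.47 ± 1.15) and cry1b (−3.57 ± 0.41). In total 2492 probe sets were called, 1345 higher and 1147 lower.

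The median over all probe sets was −0.17 at adult 1 and 5 dpa and −0.18 at 3 dpa, and relative medians below are differences from it. With arrays centred, the share of called probe sets that were higher rose from 54.0% to 67.3% at 1 dpa and from 61.1% to 75.1% at 5 dpa, with a like shift at 3 dpa. With no minimum fold change most called probe sets were lower instead, with 36.9%, 35.2% and 35.8% higher at 1, 3 and 5 dpa, and with a floor on low values 47.9% and 45.7% were higher at 3 and 5 dpa. Control probe sets for RNA added before hybridisation also separated the adult groups: their mean log2 value differed by −1.39 between the 9 regenerating and the 3 unamputated arrays, without overlap. These controls are not fin genes, but they were processed together with the fin probe sets, and the source of the shift was not tested. The shift accompanies every adult comparison with unamputated fin, and through these the differences between adult and larval change. Liposome injection, stated for the regenerating fish alone, separated the same arrays. Amputation, injection and any difference in the processing of these arrays therefore cannot be told apart in those comparisons.

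Of the 94 cell cycle genes, 67 rose and 1 fell in adult fin at 1 dpa (68 and 1 adjusted over the list alone), with a relative median of 1.74 and a camera adjusted p = 7.2e-17, or 0.39 with an estimated correlation. The nucleotide hydrolase dut rose by 3.53 ± 0.39 and the chromosome condensation gene smc4 by 3.18 ± 0.41. At 3 and 5 dpa 51 and 41 rose (54 and 41 adjusted over the list alone) and 1 fell on each day, with relative medians of 1.33 and 1.08. Proteasome genes moved alongside, with 30 of 42 higher at 1 dpa, 11 at 3 dpa and 3 at 5 dpa, and 0 lower (30, 11 and 3 adjusted over the list alone). The subunit gene psmb7 rose by 3.54 ± 0.28 at 1 dpa, and the list's camera adjusted p was 5.7e-14, or 0.39 with an estimated correlation. Of 47 chaperone genes, 20, 15 and 10 rose at 1, 3 and 5 dpa and 1, 1 and 0 fell, the same counts adjusted over the list alone. They included hsp90b1, a chaperone of the endoplasmic reticulum (2.45 ± 0.24 at 1 dpa), and the camera adjusted p at 1 dpa was 2.0e-06, or 0.29 with an estimated correlation. Mitochondrial respiration had 15 rises and 1 fall among 87 genes at 1 dpa (15 and 1 adjusted over the list alone), with the ATP synthase inhibitor atp5if1a at 2.45 ± 0.31 and a camera adjusted p = 7.1e-11, or 0.39 with an estimated correlation. The called share of this list was near that over all probe sets, 2492 of 15502, so its count is no sign of a response of the list.

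Genes known from the blastema, the proliferating tissue of the regrowing fin, had called rises at each adult day. Of 29 such genes, 13 rose and 3 fell at 1 dpa, 21 rose and 1 fell at 3 dpa, and 19 rose and 1 fell at 5 dpa, the same counts adjusted over the list alone. The camera adjusted p was 0.00027, 3.8e-10 and 6.5e-10, and 0.30, 0.085 and 0.085 with an estimated correlation. In the step from 1 to 3 dpa 4 rose, 1 fell and 24 were not called (10 and 2 adjusted over the list alone). That step had a camera adjusted p of 0.0012 toward higher, and 0.35 with an estimated correlation. From 3 to 5 dpa 0 were called (1 rise and 2 falls adjusted over the list alone). This later step had a camera adjusted p of 0.040 toward lower, and 0.54 with an estimated correlation. The actinodin genes and1 and and2, whose products build the actinotrichia fibres of the fin, fell at 1 dpa by 2.17 ± 0.54 and by 1.14 ± 0.34, values chosen after they were seen in the case of and2. They then rose at 3 dpa (4.16 ± 0.54 and 6.68 ± 0.34) and 5 dpa (4.64 ± 0.54 and 7.94 ± 0.34). The activin gene inhbaa rose by 3.69 ± 0.31 at 1 dpa and the growth factor gene mdka by 3.30 ± 0.16. In larvae the same list had 4, 6 and 6 rises and 1, 3 and 3 falls at 1, 2 and 3 dpa, among them junba and the fibronectin gene fn1b (2.30 ± 0.24 at 1 dpa). Its larval camera adjusted p was 0.10 at the lowest, at 3 dpa, and 0.39 there with an estimated correlation.

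Bone and matrix genes rose in adult fin at 3 and 5 dpa. The enamel matrix gene enam rose by 7.60 ± 0.79 at 3 dpa and 7.83 ± 0.79 at 5 dpa, the bone gene ifitm5 by 4.18 ± 0.41 and 4.65 ± 0.41, and spp1, which encodes osteopontin, by 4.29 ± 0.74 at 5 dpa. Of 22 bone genes, 1 rose and 3 fell at 1 dpa, 12 rose and 0 fell at 3 dpa, and 11 rose and 0 fell at 5 dpa, the same counts adjusted over the list alone. The camera adjusted p was 0.00066 at 3 dpa and 4.5e-07 at 5 dpa, and 0.39 and 0.23 with an estimated correlation. Of 53 extracellular matrix genes, 4 rose and 9 fell at 1 dpa, 22 rose and 1 fell at 3 dpa, and 25 rose and 1 fell at 5 dpa (23 and 27 rises adjusted over the list alone at the later days). Examples at 3 dpa were thbs3a (3.49 ± 0.41), the laminin lamb1a (2.79 ± 0.30) and the periostin postnb (2.74 ± 0.43). The camera adjusted p was 0.00014 at 3 dpa and 5.9e-09 at 5 dpa, and 0.39 and 0.23 with an estimated correlation. In larvae 5 matrix genes rose and 13 fell at 2 dpa and at 3 dpa, among them the trunk collagens named above (5 and 13 adjusted over the list alone, camera adjusted p = 0.0012 at 2 dpa, 0.17 with an estimated correlation).

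In total 2215 probe sets were called in adult fin at 3 dpa, 1256 higher and 959 lower, and 1778 at 5 dpa, 1087 higher and 691 lower. Falls at 5 dpa included prg4a (−4.02 ± 0.95), a lubricating proteoglycan, and the glycogen regulators ppp1r3cb (−2.84 ± 0.39) and ppp1r3b (−2.47 ± 0.47).

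The step from 1 to 3 dpa in adults called 385 probe sets, 324 higher and 61 lower, with enam up by 7.08 ± 0.79, ifitm5 by 6.92 ± 0.41 and col10a1a by 5.80 ± 0.43. Genes that fell were gda, a guanine deaminase (−3.75 ± 0.26), the axon growth gene gap43 (−2.79 ± 0.27) and the early response gene fosl1b (−2.42 ± 0.27). Of the matrix genes 17 rose and 1 fell (21 and 1 adjusted over the list alone), and of the bone genes 7 rose and 0 fell (10 rose adjusted over the list alone). The step's count of 385 was 139 with the 2 groups compared alone and 237 without adult 3 dpa replicate c. From 3 to 5 dpa, 8 probe sets were called, 6 higher and 2 lower, and 1646 had an unadjusted p under 0.05. The named genes were gda (2.34 ± 0.26) and mylka (1.53 ± 0.21), which rose, and ntrnl2 (−3.50 ± 0.49) and hspb8 (−1.84 ± 0.24), which fell. With the replicate letters of these 2 groups as a block or with the 2 groups compared alone, 1 probe set was called, and leaving out any array but adult 5 dpa replicate c gave between 1 and 5.

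**Figure D3:**
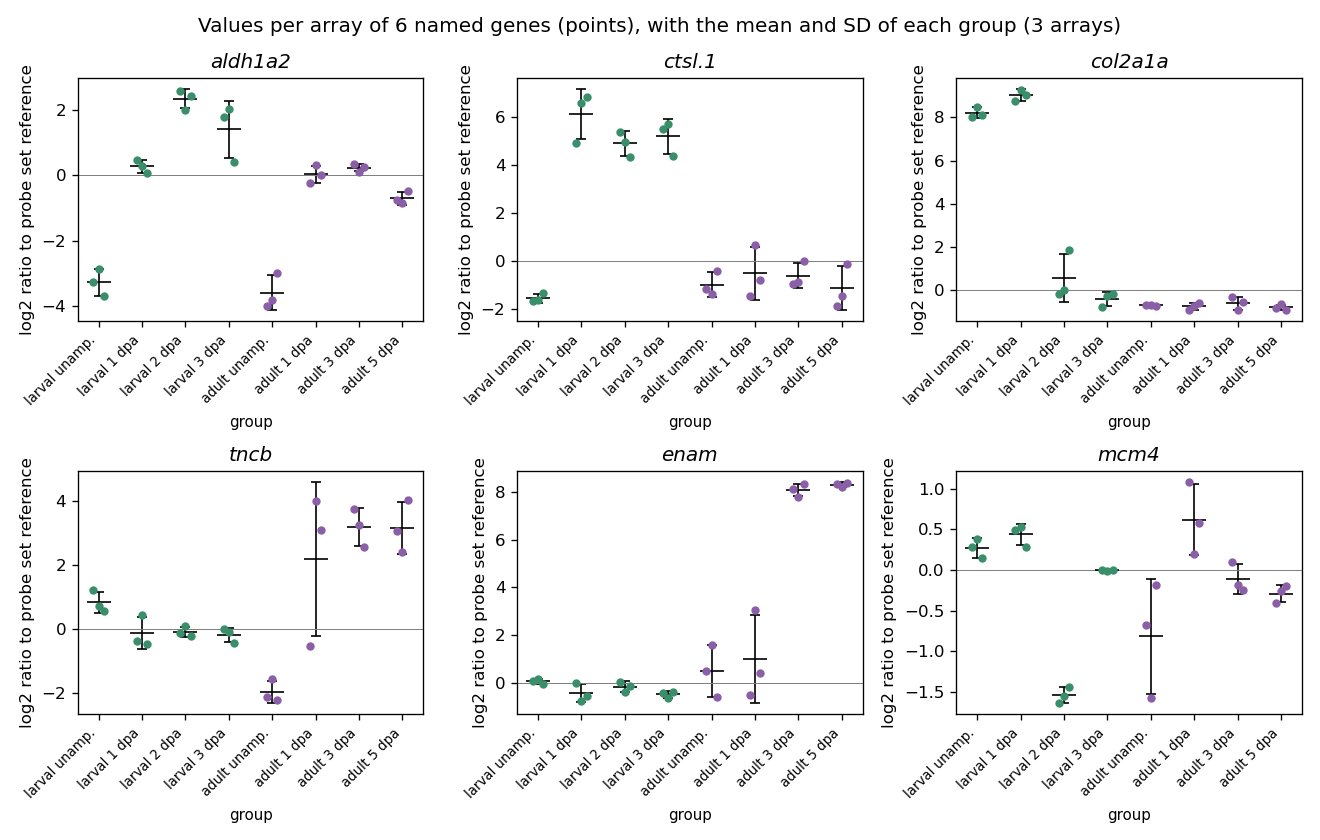
Log2 ratio of 6 named genes on each array (points), with group means and SD (black, 3 arrays), in larval (green) and adult (purple) fin. The gene aldh1a2 was higher in all regenerating groups of both ages, ctsl.1 in larval groups alone, and enam in adult fin at 3 and 5 dpa.

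Calls shared by the ages were more than independent calls would give, and so were most calls in opposite directions. Fisher's exact test takes probe sets as independent units, which they are not, so its p values overstate the evidence. At 1 dpa 54 probe sets rose in both ages where 32.7 were expected (Fisher's exact test, two-sided, adjusted p = 0.00032), and 69 fell in both where 18.1 were expected (adjusted p = 2.8e-22 in Fisher's exact test). At 3 dpa 115 rose in both where 63.8 were expected (Fisher's exact test, adjusted p = 8.8e-10), and 85 fell in both where 52.8 were expected (adjusted p = 1.6e-05 in Fisher's exact test). At 1 dpa 18 probe sets rose in adults and fell in larvae where 21.3 were expected, and 54 did the reverse where 27.9 were expected (Fisher's exact test, adjusted p = 0.57 and 4.2e-06). At 3 dpa these were 161 where 69.2 were expected and 102 where 48.7 were expected (Fisher's exact test, adjusted p = 1.7e-24 and 1.1e-12). The tests of opposite calls were chosen after the counts were seen. At 3 dpa, where opposite calls numbered 263 and shared calls 200, the excess of shared calls is therefore no sign of one common direction. Across all probe sets, which are not independent replicates, adult and larval changes had r = 0.089 at 1 dpa and r = −0.014 at 3 dpa. With arrays centred, 71 of the shared 1 dpa calls were rises and 55 were falls. Few shared rises remained at 1 dpa with a floor on low values (4 rises, 19 falls) and with probe sets above the median mean (2 and 20). At 3 dpa falls became the majority of shared calls with no minimum fold change (419 rises, 539 falls), with a floor on low values (14 and 30) and with probe sets above the median mean (12 and 19).

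By the smaller of its adult and larval change, aldh1a2 was the largest shared rise among named genes at both days, with 3.63 ± 0.25 in adults at 1 dpa and 3.84 ± 0.25 at 3 dpa beside the larval values above, and it stood at 2.90 ± 0.25 in adults at 5 dpa. At 1 dpa the shared rises also held fn1b (3.20 ± 0.18 in adults, 2.30 ± 0.24 in larvae), socs3b (2.03 ± 0.28 and 2.18 ± 0.28) and spi1b (1.92 ± 0.25 and 2.41 ± 0.38). At 3 dpa they held the secreted Wnt modulator dkk3b (3.35 ± 0.37 in adults, 3.52 ± 0.24 in larvae), igf2b (3.53 ± 0.27 and 2.49 ± 0.34) and the globin cygb1 (4.22 ± 0.27 and 2.15 ± 0.27). Shared falls at 3 dpa held the Wnt inhibitor wif1 (−2.04 ± 0.24 in adults, −2.10 ± 0.10 in larvae), rcan3 (−2.88 ± 0.82 and −2.64 ± 0.14) and ppp1r3b (−2.25 ± 0.47 and −3.45 ± 0.21). The sterol gene cyp51 was also among them (−2.02 ± 0.61 and −2.61 ± 0.24), although another probe set of the gene read 0.12 in both ages.

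At all 3 days in both ages 24 probe sets rose and 11 fell, where 8.07 and 3.30 were expected (Fisher's exact test, adjusted p = 3.9e-06 and 0.00047). The rises held more than 1 probe set of cygb1 and the falls more than 1 of cyp51. Within an age, 549 rose and 433 fell at all 3 days in adults, and 228 rose and 118 fell in larvae. Simulated data without change averaged 0.05 and 0 such calls, but adjusted p values call almost nothing in such data. How far the shared unamputated arrays raised the real counts was therefore not measured. The genes higher throughout included, as examples chosen after their values were seen, aldh1a2, fn1b, dkk3b, socs3b, spi1b, the cathepsin gene ctsla and the matrix gene thbs3a, and those lower throughout included rcan3, ppp1r3b, epas1a and the cryptochrome gene cry5. With a floor on low values, 0 rises and 8 falls were shared at all days, and the rise of aldh1a2 at larval 1 dpa (0.61) and at adult 1, 3 and 5 dpa (0.58, 0.79 and 0.022) was no longer called.

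The difference between adult and larval change was called for 2779 probe sets at 1 dpa, 1383 with the higher change in adults and 1396 with the higher change in larvae. At 3 dpa it was called for 3425, 1786 and 1639. With arrays centred, the share higher in adults went from 49.8% to 61.6% at 1 dpa and from 52.1% to 62.5% at 3 dpa, whereas with no minimum fold change it was 42.9% and 41.5%. Adult change exceeded larval change most in ntrnl2 (6.76 ± 0.52) at 1 dpa and in col2a1a (8.76 ± 0.49) and enam (8.15 ± 0.84) at 3 dpa. The col2a1a difference was a larval fall, from log2 ratios of 8.04 to 8.50 in unamputated fin to −0.81 to −0.21 at 3 dpa. In adults they were −0.76 to −0.69 in unamputated fin and −0.94 to −0.34 at 3 dpa. Larval change exceeded adult change most in ctsl.1 (−7.19 ± 0.80) at 1 dpa and in tat (−9.42 ± 1.32) at 3 dpa. For aldh1a2 no difference was called, at 0.07 ± 0.47 and −0.86 ± 0.47. The aldh1a2 difference at 3 dpa was called with quantile normalization (−3.26), with a floor on low values (−1.18) and without larval 3 dpa replicate 3 (−1.36). The cell cycle list differed by a relative median of 1.48 at 1 dpa, with 58 genes higher in adults and 1 in larvae (61 and 1 adjusted over the list alone), and a camera adjusted p = 9.1e-16, or 0.38 with an estimated correlation. Labelling kit and RNA input differed between the ages, and controls for RNA added before labelling had a mean log2 value of 0.63 in adult unamputated fin and of 1.19 to 1.53 in adult regenerating fin, against −0.40 and −0.56 to −0.72 in larvae.

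Other adult lists had called members in both directions. Over all probe sets 2492 of 15502 were called at adult 1 dpa. The called shares of the Fgf, neuron and glia, oxidative stress and pigment cell lists were near or below that share at 1 dpa. Their counts there are therefore no sign of a response of the list. The retinoic acid list of 23 genes had 4 rises and 3 falls at 1 dpa (4 and 3 adjusted over the list alone), with the binding protein gene crabp2b at 3.56 ± 0.16 and the carrier gene rbp4 at −2.72 ± 0.54. The retinoic acid degrading gene cyp26a1 rose by 1.97 ± 0.18 at 3 dpa and 2.72 ± 0.18 at 5 dpa. In larvae 2 genes of that list rose on each day (2 adjusted over the list alone), and against unamputated fin the lowest camera adjusted p in either age was 0.12, or 0.39 with an estimated correlation. From adult 3 to 5 dpa the list had a camera adjusted p = 0.029 toward higher, or 0.23 with an estimated correlation, and 0 of its genes were called. Of 36 Wnt genes 8, 12 and 10 rose in adults at 1, 3 and 5 dpa and 4, 1 and 1 fell (8, 12 and 10 rises adjusted over the list alone). The nuclear effector lef1 was at 4.05 ± 0.25 at 3 dpa, and the list had a camera adjusted p = 0.0085 there, or 0.42 with an estimated correlation. Of 24 Fgf genes 1, 3 and 5 rose and 1, 1 and 0 fell (the same counts adjusted over the list alone), including the pathway target etv4 (2.37 ± 0.34 at 3 dpa), with a camera adjusted p = 0.042 at 5 dpa, or 0.44 with an estimated correlation. Of 36 Bmp, activin and Tgfb genes 2 rose and 8 fell at 1 dpa and 6 rose and 2 fell at 5 dpa, the same counts adjusted over the list alone, with tgfb1a at 2.79 ± 0.49 at 5 dpa (camera adjusted p = 0.076, 0.39 with an estimated correlation). The Hedgehog genes shha (1.79 ± 0.35) and gli2a (1.74 ± 0.27) were among 3 that rose at 3 dpa in adults, where 0 fell (3 adjusted over the list alone). In the list of 33 neuron and glia genes 2, 3 and 4 rose and 3, 3 and 2 fell at adult 1, 3 and 5 dpa (2, 3 and 4 rises and 3 falls at each day adjusted over the list alone). Its nerve sheath myelin gene mbpa fell at each adult day, by 1.42 ± 0.44, 1.59 ± 0.44 and 1.88 ± 0.44. Of 8 aryl hydrocarbon receptor targets 2 fell at adult 1 dpa, cyp1a and nqo1 (−1.30 ± 0.33), and the list had a camera adjusted p = 0.16, or 0.62 with an estimated correlation. Of 31 oxidative stress genes 2 rose and 2 fell, with the thioredoxin gene txnb at 3.55 ± 0.56 (camera adjusted p = 0.41, 0.64 with an estimated correlation). Of 15 pigment cell genes 2 rose and 1 fell at adult 1 dpa (camera adjusted p = 0.59, 0.80 with an estimated correlation), and gch2, an enzyme of pteridine pigment synthesis, fell in larvae at all 3 days, to −3.10 ± 0.33 at 3 dpa. Of the proteases 8 rose and 2 fell at adult 1 dpa, with the collagenase mmp13a at 3.46 ± 0.57.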

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

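Among the tests in this part, all but those of the level of cell cycle genes in unamputated fin, of a single discordant array and of the hour of the day were chosen after the result was seen.

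The results here were marked because a test of the difference between adult and larval change passed its threshold. At 1 dpa 2779 probe sets did. Adult change exceeded larval change in ntrnl2 (6.76), jac4 (6.45), tph1b (5.79), tncb (5.09, but −0.28 by another probe set) and f5 (4.96), and larval change exceeded adult change in ctsl.1 (−7.19), tat (−5.95), si:dkey-247k7.2 (−5.76), zgc:136930 (−5.63) and si:dkey-183i3.5 (−5.55). Lists that passed with the preset correlation had median differences of 0.75 (blastema), 1.34 (cell cycle), 0.71 (chaperones), 0.25 (mitochondrial respiration), 0.93 (proteasome), −0.67 (neurons and glia) and −0.30 (notochord and cartilage).

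At 3 dpa 3425 probe sets differed. The differences were 8.76 in col2a1a, 8.15 in enam, 8.001 in smyhc1, 7.43 in col9a2 and 7.32 in atp2a1, and −9.42 in tat, −6.70 in irf1b, −6.35 in ctsl.1, −6.12 in si:dkey-247k7.2 and −5.46 in zdhhc2. List medians were 1.52 (blastema), 0.37 (Hedgehog), 0.92 (extracellular matrix), 1.51 (cell cycle), −1.0045 (inflammation), 3.14 (skeletal muscle), 0.74 (erythrocytes), 0.35 (endothelium), 0.56 (notochord and cartilage), 0.37 (chaperones), 0.41 (mitochondrial respiration) and 0.77 (proteasome). Of 54 list tests on differences 19 passed, and 0 passed with an estimated correlation.

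Other splits of the same arrays were counted for each result, with the real value first and the highest other after it. For 3 arrays against 3 there are 10 splits, in which 1 was as large, and 10 are too few for a share under 0.05. The counts were 622 and 2, 1945 and 0, and 1641 and 0 for larval 1, 2 and 3 dpa, and 2492 and 0, 2215 and 5, and 1778 and 0 for adult 1, 3 and 5 dpa. For the steps they were 1385 and 0 (larval 1 to 2 dpa), 46 and 1 (larval 2 to 3 dpa), 385 and 1 (adult 1 to 3 dpa) and 8 and 1 (adult 3 to 5 dpa).

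Of the 200 splits within both ages, 100 were drawn. As many differing probe sets were called in 2 of them at 1 dpa (2779, highest other 3362) and in 1 at 3 dpa (3425, highest other 3368), the real split included. As many shared calls were made in 1 of them at 1 dpa (123, highest other 72) and in 2 at 3 dpa (200, highest other 263). The splits with 3362 and 3368 were the ones with the larval labels exchanged, which turn the difference of the 2 changes into their sum, so they show a structure of the samples and not chance. Exchanging them likewise counts opposite calls as shared, of which there were 161 and 102 at 3 dpa. In 100 regroupings within both ages, 1 gave as many shared calls at all days (35, highest other 0), and 1 gave as many list tests passed (72, highest other 71). The share was under 0.05 for the 2 counts of differing probe sets and, by a margin of 1, for the number of list tests. These splits break up the response to amputation in both ages at once. A low share therefore speaks against no response in either age, and does not test whether the ages changed alike. For the list tests it decides little, since another regrouping passed 71. For shared calls these counts decide nothing about sharing: in 97, 98 and 99 of the 99 others at 1 dpa, 3 dpa and all days, at least 1 of the comparisons called 0 probe sets, which leaves none to share.

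The first pattern weighed was the fall of skeletal muscle genes in larval fin at 2 and 3 dpa, for which scaling of the arrays was argued against, since the muscle median nearest to 0 with arrays centred or quantile normalized was −2.50. Less trunk tissue in the collected samples needs other trunk tissues to fall too. With the preset correlation, 8 of 8 list tests of notochord and cartilage, erythrocytes, endothelium, and neurons and glia shifted down. Per list and day there were 5 to 11 called falls and 0 or 1 called rise. With an estimated correlation 0 of the 8 passed (camera adjusted p of 0.085 to 0.42). The muscle list itself did not pass that setting, so this weighs neither way. Less trunk tissue cannot be told apart from a wider fall of tissue genes. The epidermis, a fin tissue that less trunk would not lower, also shifted down (15 fell and 5 rose at 2 dpa, 14 and 2 at 3 dpa). The requirement that the epidermis not fall was added after these values were seen. The epidermis test was already toward lower at 1 dpa, when muscle genes had not fallen. Its shift therefore did not begin with the muscle fall, and by itself decides little. In addition, 14 of the 24 notochord and cartilage genes are also held by another list, and fins hold vessels, nerves and blood themselves. The processing set of the 2 and 3 dpa arrays cannot be told apart from day and vehicle, since their hybridisation controls differed by −0.20 from the other larval arrays and overlapped them. The day, age and vehicle exposure of these fish stay open as untested biological explanations.

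The second pattern was the opposite movement of cell cycle genes, up in adult and down in larval regenerates at 2 and 3 dpa (at larval 1 dpa 0 were called). Their level in unamputated fin was 0.87 higher in larvae than in adults relative to all probe sets, between the bounds of 0 and 1 set beforehand, and it cannot be told apart from labelling kit and RNA input, which differ between the ages. For the rise from larval 2 to 3 dpa, a gain in the share of trunk tissue was argued against, since the muscle median changed by −0.049. A further loss of trunk tissue need not show in muscle genes, whose median was already −3.24 at 2 dpa, and stays undecided. The rise was not explained by the discordant array, larval 3 dpa replicate 3, since the median of cell cycle genes was 0.48 with and 0.48 without it. Age, growth of the larvae and vehicle exposure stay open and were not tested.

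The third pattern was the fall of clock repressor and output genes in adult fin at 1 dpa. The unamputated adult arrays cannot be told apart as a cause: the list's median change was 0.69 from 1 to 3 dpa, a step without these arrays, but 0 of 16 genes were called in it, and array medians, looked at after that value was seen, differed by 0.62 ± 0.29 and overlapped (highest at 1 dpa −0.37, lowest at 3 dpa −0.40). For another hour of the day at collection, the median of activators and evening genes minus that of repressors and outputs was 1.64. It met the bound of 1 written beforehand for this explanation. A further requirement, a median of activators and evening genes of at least 0.5, was added after that value was seen. The reason was that −1.47 of it is the fall of the repressors and outputs itself, while the other list had a median of 0.17. In that list bmal1a (1.37), bmal2 (1.69) and nfil3-5 (1.86) rose, and rorab (−2.35) and nfil3-6 (−1.72) fell. Neither fall was in a bmal, clock or npas2 gene. Judged by the added requirement, the hour of the day may explain the fall but cannot be told apart from a response to amputation, as no collection times are given.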

How the results depend on the processing

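Among the alternatives below, only the removal of probe sets with a ratio under 1 in 15 or more arrays was chosen after seeing the data. The 3 alternatives that changed most counts did so largely by construction. An exception was the adult step from 3 to 5 dpa, whose count went from 8 to 17 with a floor on low values. The cause of that increase was not tested. Dropping the minimum fold change admits smaller changes, a floor at the 25th percentile shortens changes that start from low ratios, and keeping probe sets above the median mean tests fewer of them. Because the deposited values are ratios, the latter 2 act on low ratios and not on dim signals, and what signal over background limits cannot be read from such values.

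With no minimum fold change, larval counts against unamputated fin were 2097, 4899 and 4371 at 1, 2 and 3 dpa, and adult counts were 7160, 6783 and 5321 at 1, 3 and 5 dpa. The larval steps had 3629 and 73, the adult step from 1 to 3 dpa had 696, the differences between ages had 4816 and 6126, and shared calls numbered 693, 958 and 196 at 1 dpa, 3 dpa and all days. With the floor, in the same order, counts were 256, 1030 and 843 in larvae, 1545, 1258 and 978 in adults, 797 and 6 in the larval steps, and 164 and 17 in the adult steps. The difference at 1 dpa had 1714, and shared calls numbered 23, 44 and 8. With probe sets above the median mean, counts were 322, 1086 and 916 in larvae, 1610, 1300 and 1084 in adults, 820 and 15 in the larval steps and 181 in the adult step from 1 to 3 dpa. The differences had 1603 and 1942, and shared calls numbered 22, 31 and 6. The 24 shared rises and 11 shared falls at all days became 0 and 8 with the floor, 1 and 5 with the filter, and 92 and 104 with no minimum fold change.

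Other settings changed few counts beyond 1.5 times. With quantile normalization the larval step from 2 to 3 dpa had 74, the adult step from 3 to 5 dpa had 17 and shared calls at all days were 23. With only the 2 groups compared, the larval step from 2 to 3 dpa had 2, the adult step from 1 to 3 dpa had 139 and that from 3 to 5 dpa had 1. The adult step from 3 to 5 dpa had 64 with all 24 arrays in one fit, 4 with a variance trend and 5 without probe sets under 1 in 15 or more arrays. With the replicate letters as a block, which would take up any pairing of adult 3 and 5 dpa arrays, it had 1. The cause was not tested. Centring the arrays kept all 15 counts within 1.5 times.

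Leaving out 1 array at a time gave these ranges against unamputated fin: 513 to 693, 1810 to 1927 and 1526 to 1809 in larvae at 1, 2 and 3 dpa, and 2106 to 3024, 1847 to 2309 and 1428 to 1823 in adults at 1, 3 and 5 dpa. Steps ranged from 1236 to 1628 (larval 1 to 2 dpa), 23 to 122 (larval 2 to 3 dpa), 237 to 535 (adult 1 to 3 dpa) and 1 to 11 (adult 3 to 5 dpa). Differences ranged from 2458 to 3289 and from 3162 to 3651, and shared calls from 97 to 150, 173 to 222 and 27 to 38. Counts moved beyond 1.5 times in the larval step from 2 to 3 dpa without 2 dpa replicate 1 (23), 2 dpa replicate 3 (29) and 3 dpa replicate 1 (122), and in the adult step from 1 to 3 dpa without 3 dpa replicate c (237). In the adult step from 3 to 5 dpa they did so without 3 dpa replicates a (1), b (5) and c (2) and without 5 dpa replicates a (3) and b (3).

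When a named gene was read from another of its probe sets, 128 changes kept direction and call, 64 were no longer called, 2 were newly called and 15 reversed. The reversed ones were tncb in adults (−0.38, −0.30 and −0.28 at 1, 3 and 5 dpa) and in the difference at 1 dpa (−0.28), cyp51 at 3 dpa in adults (0.12) and larvae (0.12), fn1a (0.17) and incenp (0.040) at larval 2 dpa, and cst14b.1 in adults (−0.36 at 1 dpa, −0.15 at 3 dpa). They also included sox2 at larval 3 dpa (0.052), prph in adults (−0.42 at 3 dpa, −0.33 at 5 dpa), cnmd at adult 1 dpa (0.011) and hapln1a at adult 3 dpa (−0.092). Among the lists, leukocyte genes reversed at larval 2 and 3 dpa with only genes above the median mean (adjusted p of 0.86 and 0.71, from a range over alternatives of 0.0069 to 0.86 and 0.0090 to 0.71). Mitochondrial respiration at larval 3 dpa reversed without larval 3 dpa replicate 3 (adjusted p = 0.035, range 0.035 to 0.99). The cause was not tested. With the floor 243 of 831 named changes were no longer called, and with quantile normalization 46 were not. Neither centring nor quantile normalization reversed a named gene or a list.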

Other observations

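Every gene named in this part was chosen after its values were seen. In adult fin at 1 dpa, 7 of 16 clock repressor and output genes fell, 0 rose and the median was −1.47, with cry1b at −3.57, tefa at −3.05, bhlhe40 at −2.99, cry2 at −2.70, cry5 at −2.58 and ciarta at −4.47. The cryptochromes repress the clock's own activators, and tefa drives its outputs. At 3 dpa 5 fell, 0 rose and the median was −0.77, and at 5 dpa 3 fell, 1 rose and the median was −0.23. Of 10 activators and evening genes at 1 dpa, bmal1a (1.37), bmal2 (1.69) and nfil3-5 (1.86) rose, and rorab (−2.35) and nfil3-6 (−1.72) fell. In larvae 1, 1 and 2 of the repressors and outputs rose and 2, 1 and 1 fell at 1, 2 and 3 dpa, with cry5 at −1.91, −2.03 and −2.28, cry1a at −1.52 at 1 dpa, cry1b at 1.15 and 1.14 at 2 and 3 dpa, and bhlhe41 at 1.02 at 1 dpa and 1.48 at 3 dpa.

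Adult replicates at 3 and 5 dpa carried the same letters, and their residuals correlated across probe sets with r of 0.433, 0.216 and 0.156 for a, b and c. The letter b of adult 1 dpa had r of 0.405 with 5 dpa and of 0.048 with 3 dpa, while 6 of 18 larval pairs of the same number exceeded 0.1. Probe sets are not independent replicates in these correlations.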
